A study of Mus musculus with 130 samples.

How the data were processed

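Total RNA from atria and ventricles of wildtype and transgenic mice, extracted with Tri-reagent per the labels, was measured with Cy-3 labelled bead arrays. Each array was assigned to its tissue, genotype, animal and zeitgeber time from its title, and 0 columns of the tables remained without a sample. The deposited files hold for each tissue a non-normalized and a normalized table and the series value table. In the non-normalized tables each value is, per the file headers, the average bead signal of a probe, an intensity on a linear scale with no value at or below 0, made by the submitters with BeadStudio version 3 per the labels. Beside it stands, per the file headers, a detection p-value for each probe and array against negative control beads. The normalized tables of the authors hold an intensity normalized between the arrays of a tissue with background subtracted, by a method the files do not name; 39.8% of the values in atria and 43.2% in ventricles lie below 0. The series value table equals these normalized tables (largest difference 1.8e-15), so it gave no separate alternative. Nothing in the files names the slide of an array, and a slide block was not fitted.

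Values were computed from the non-normalized tables with limma 3.58.1 in R 4.3.3: neqc, which corrects background from the detection p-values with an offset of 16, normalizes by quantiles and takes log2. Probes with a detection p under 0.05 in at least 8 arrays of the tissue were kept (13879 in atria and 14357 in ventricles). Probes were given current gene symbols through their accession (22668 probes), a current symbol (5023), a synonym (5523) or the name in the file (11175), and 1731 had none. The brightest probe in each tissue stood for a gene, so that some genes have different probes in atria and ventricles. Reference genes were used for names and for neighbouring genes (GRCm38.p6). Each gene was fitted by limma with a mean level and a 24 h cosine and sine for each genotype, and moderated F-tests or moderated tests of the terms were adjusted by Benjamini and Hochberg with a threshold of 0.05. Rhythm differences were tested as the difference of the cosine and sine terms, over all genes and over the wildtype-rhythmic genes alone. The amplitude is the distance from mean to peak in log2 units. The share of rhythm kept is the projection of the transgenic cosine and sine on the wildtype ones over the wildtype amplitude. For comparisons between tissues both tables were normalized together.

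Before the data were examined, 36 gene lists were fixed, along with the comparisons, their tests and most alternatives. Lists with at least 3 measured genes were tested for level with camera at a preset correlation of 0.01 and again with an estimated correlation, and for rhythm with Fisher's exact test, two-sided, adjusted over the lists of a tissue. Genes are not independent in these tests. The genes named follow a rule fixed in advance: the core clock and clock output lists, the 10 largest wildtype amplitudes, all rhythm differences up to 10, the 8 largest rises and falls in level, up to 4 members of each list described, the 6 largest differences between tissues, and Clock. Beyond the rule, the genes rhythmic in a list, the members behind a small count, Rcan1 and Gja5 in the text on groups were chosen after their values were seen. The values of some genes that the rule covers are not reported here.

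The method was tested on simulated data made by adding changes of known size to the real gene levels with residuals shuffled between arrays. Of added rhythms of 0.25 in log2 amplitude 86.0% were called in wildtype atria and 77.5% in ventricles, of added rhythm differences of this size 59.0% and 70.0%, and of added level differences 79.0% and 77.0%. The added rhythm differences were full losses of rhythm in 200 genes. These shares therefore do not hold for partial changes or for changes in few genes, where the adjusted threshold is harder to pass. Arrays limit the precision by their number and by the signal over background. The alternatives were the authors' normalized table (log2 after a floor at the 0.05 quantile of its positive values), normalization without background correction, normexp with an offset of 50, other filters on dim probes, every probe on its own, array weights, a trended and robust spread, time as a factor, added 12 h terms, and leaving out each time point and each animal. Animals, tissue normalization and the choice of rhythmic genes had alternatives of their own. Added after the data were seen were alternatives on arrays of low signal or low weight, on array signal and on marker scores. Each comparison was repeated for 100 splits of the animals, the real one included. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 in Python 3.11.15.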

Results

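Gene expression was measured on 1-colour bead arrays in the hearts of wildtype mice and of transgenic mice that, per the labels, lack a working circadian clock in their heart muscle cells. Atria and ventricles were taken every 3 h at 8 zeitgeber times (ZT, the time within the light-dark cycle). There were 32 arrays of wildtype atria, 32 of transgenic atria, 34 of wildtype ventricles and 32 of transgenic ventricles, with 3 to 5 arrays for each tissue, genotype and time point. Of the animals, 64 gave both tissues and 2 gave ventricles only. The series description names 128 samples with 4 per time point, and 130 labelled arrays are present. Each table held 46120 probes. A median of 10681.5 probes was detected per atria array (range 9214 to 13171) and of 9989 per ventricle array (range 7803 to 15061). The median non-normalized signal was at least 94.4 in each atria array and ranged from 39.1 to 148 in ventricles. There, 6 arrays (3 wildtype and 3 transgenic) lay between 39.1 and 43.1. They are called arrays of low signal below for this median alone. They had 13296 to 15061 detected probes, more than any other ventricle array (at most 11395). After the filter on detection, 11275 genes were tested in atria and 11604 in ventricles. The number of arrays limits the precision of every value.

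Clock, a transcription factor of the core circadian feedback loop, stood far above every other gene in its difference between the genotypes. In atria its log2 signal was 14.28 ± 0.314 (SD, n = 32) in transgenic and 5.97 ± 0.205 (SD, n = 32) in wildtype arrays, a difference of 8.31 (SE 0.0620) or 318-fold. In ventricles the difference was 7.78 (SE 0.112) or 219-fold, from 5.97 ± 0.253 (SD, n = 34) to 13.75 ± 0.602 (SD, n = 32). The probe was detected in all 32 transgenic arrays of each tissue and in 6 of 32 wildtype atria and 14 of 34 wildtype ventricle arrays, so that the wildtype signal lay near background and the folds depend on it. A second Clock probe, detected in every array, was higher in transgenic tissue by 0.80 in atria and by 0.60 in ventricles, and the last Clock probe was detected in no array. The labels do not name the transgene.

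The wildtype atria were compared across the day for the first question of the study, which genes oscillate in normal tissue. Dbp, a transcription factor driven by the clock, had the largest rhythm, with an amplitude of 2.38 on the log2 scale (SE 0.0972), a 27.2-fold range from trough to peak and a peak at ZT 8.57. It was followed by Per2, a repressor in the core loop (amplitude 1.53, SE 0.0732, peak at ZT 11.7), Spon2, a secreted matrix protein (1.40, SE 0.108, ZT 22.7), and Tef, a relative of Dbp (1.06, SE 0.0562, ZT 10.7). Fbn1, which forms microfibrils of the matrix, had an amplitude of 0.99 (SE 0.0959) with its peak at ZT 0.965. Pdk4, a kinase that restrains pyruvate oxidation, had one of 0.99 (SE 0.139) at ZT 2.02. Per3 (0.96, SE 0.0616, ZT 9.91), Nfil3, a repressor that binds the same sites as Dbp (0.91, SE 0.0741, ZT 20.4), Adam19, a membrane protease (0.83, SE 0.0588, ZT 21.7), and Usp2, a deubiquitinase (0.75, SE 0.0989, ZT 10.3), complete the 10 largest amplitudes. Arntl, the partner of Clock, peaked at ZT 22.5 (0.55, SE 0.0522), far from Per2 in the cycle, and Nr1d1, a repressor of Arntl, at ZT 5.25 (0.66, SE 0.0571). Wildtype Arntl was detected in 15 of 32 atria arrays, so that background limits its trough.

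In all, 502 genes (4.45% of those tested) were rhythmic in wildtype atria by limma's moderated F-test at an adjusted p under 0.05, of which 169 had a range of at least 1.5-fold and 41 of at least 2-fold. Their peaks gathered at ZT 9 to 12 (113 genes) and ZT 21 to 24 (86 genes) and were sparsest at ZT 15 to 18 (28 genes). Of the 14 measured core clock genes 8 were rhythmic, also 8 when adjusted over the list alone (Fisher's exact test against all other genes, adjusted p = 3.8e-07). Of the 10 measured clock output genes 9 were rhythmic, 10 when adjusted over the list alone (adjusted p = 2.0e-10). Genes of the extracellular matrix and fibroblasts were rhythmic in 14 of 33, 16 when adjusted over the list alone (adjusted p = 6.2e-10), among them Fbn1, the basement membrane collagen Col4a1 (0.46), the crosslinking enzyme Loxl1 (0.45) and the elastin gene Eln (0.57). Glucocorticoid-responsive genes were rhythmic in 7 of 16, 8 when adjusted over the list alone (adjusted p = 2.2e-05), with Pdk4, Klf9 (0.39), Zbtb16 (0.63) and the metallothionein Mt1 (0.27) as examples. Heat shock and protein folding genes were rhythmic in 5 of 25, 9 when adjusted over the list alone (adjusted p = 0.0287), and the chaperones Hspb1 (0.33), Hspe1 (0.33) and Hsp90aa1 (0.41) were among them. The count of 502 moved with the samples and the model. It was 764 without wildtype animal 205, 765 without ZT12, 225 without ZT9, 300 without ZT21, 307 without ZT15 and 324 without ZT6. It was also 334 without the filter on dim probes, 264 with time as a factor and 1449 with array weights.

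**Figure D1:**
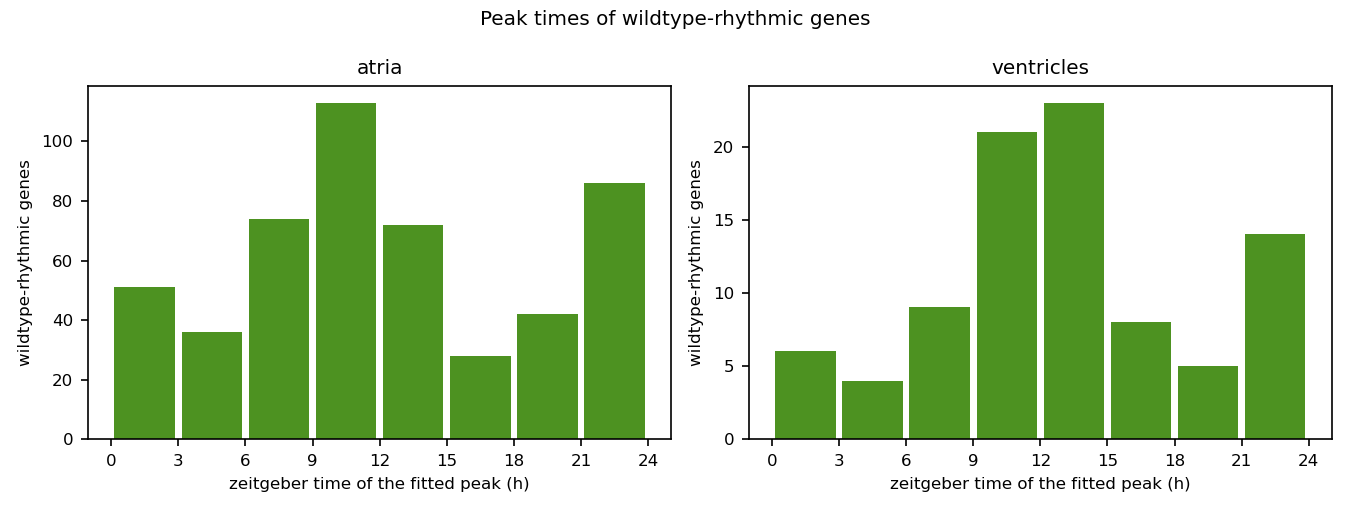
Number of wildtype-rhythmic genes (y axis) by the zeitgeber time of the fitted peak in bins of 3 h (x axis, h), for atria (left, 502 genes) and ventricles (right, 90 genes). The fullest bins were ZT 9 to 12 in atria with 113 genes and ZT 12 to 15 in ventricles with 23.

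In wildtype ventricles the same question gave fewer genes with Dbp again first (amplitude 2.14, SE 0.121, 19.6-fold, peak at ZT 9.20). Per2 (1.42, SE 0.0727, ZT 11.9), Spon2 (1.34, SE 0.112, ZT 22.4) and Tef (0.89, SE 0.0828, ZT 11.5) came next, followed by Gsta3, a glutathione transferase (0.85, SE 0.0749, ZT 14.0), Nfil3 (0.76, SE 0.0764, ZT 19.8), Pdk4 (0.76, SE 0.151, ZT 2.17) and Fbn1 (0.72, SE 0.0825, ZT 1.15). Timp3, an inhibitor of matrix proteases (0.66, SE 0.0664, ZT 12.0), and Mid1ip1, a regulator of fat synthesis (0.65, SE 0.110, ZT 11.5), complete the 10 largest.

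By limma's moderated F-test 90 genes (0.776%) were rhythmic in wildtype ventricles, 57 of them over at least 1.5-fold and 19 over at least 2-fold. The count was 186 with array weights. Core clock genes were rhythmic in 6 of 14 (among them Per2, Per3, Nr1d1, Bhlhe40 and Arntl), 7 when adjusted over the list alone (Fisher's exact test, adjusted p = 8.9e-09), and clock output genes in 7 of 10, also 7 when adjusted over the list alone (adjusted p = 5.3e-12). The extracellular matrix list had 4 of 31, 7 when adjusted over the list alone (Timp3, Fbn1, Col4a1 at 0.45 and Col4a2 at 0.32, adjusted p = 0.00103). The glucocorticoid-responsive list had 3 of 16, 7 when adjusted over the list alone (Pdk4, Cebpb at 0.49 and Zbtb16 at 0.32, adjusted p = 0.00200). The triglyceride list had 3 of 18, 4 when adjusted over the list alone (Dgat2 at 0.38, Plin4 at 0.23 and Pnpla3 at 0.23, adjusted p = 0.00230). Without the 6 ventricle arrays of low signal 82 genes were rhythmic.

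The next comparison asked how rhythms differed in the transgenic hearts. The rhythms of the most strongly oscillating genes were still present in transgenic atria. Dbp had an amplitude of 2.02 (SE 0.0994), Per2 of 1.35 (SE 0.0718), Spon2 of 1.27 (SE 0.107), Fbn1 of 0.92 (SE 0.0939) and Tef of 0.86 (SE 0.0568). Adam19 had an amplitude of 0.22 (SE 0.0576) in transgenic against 0.83 (SE 0.0588) in wildtype atria (test of the rhythm difference, adjusted p = 9.8e-08). Slc41a3, a member of a magnesium transporter family, had 0.13 (SE 0.0521) against 0.72 (SE 0.0531) (adjusted p = 3.4e-06), and 4732462B05Rik 0.17 (SE 0.0446) against 0.46 (SE 0.0456) (adjusted p = 0.0413). In ventricles Slc41a3 had an amplitude of 0.07 (SE 0.0720) in transgenic against 0.64 (SE 0.0684) in wildtype arrays (adjusted p = 2.1e-04). Cdkn1a, an inhibitor of the cell cycle, showed the opposite, with an amplitude of 0.56 (SE 0.0654, peak at ZT 17.5) in transgenic against 0.13 (SE 0.0644) in wildtype ventricles (adjusted p = 0.00793). Wildtype Cdkn1a was detected in 14 of 34 ventricle arrays, so that background limits its amplitude there.

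**Figure D2:**
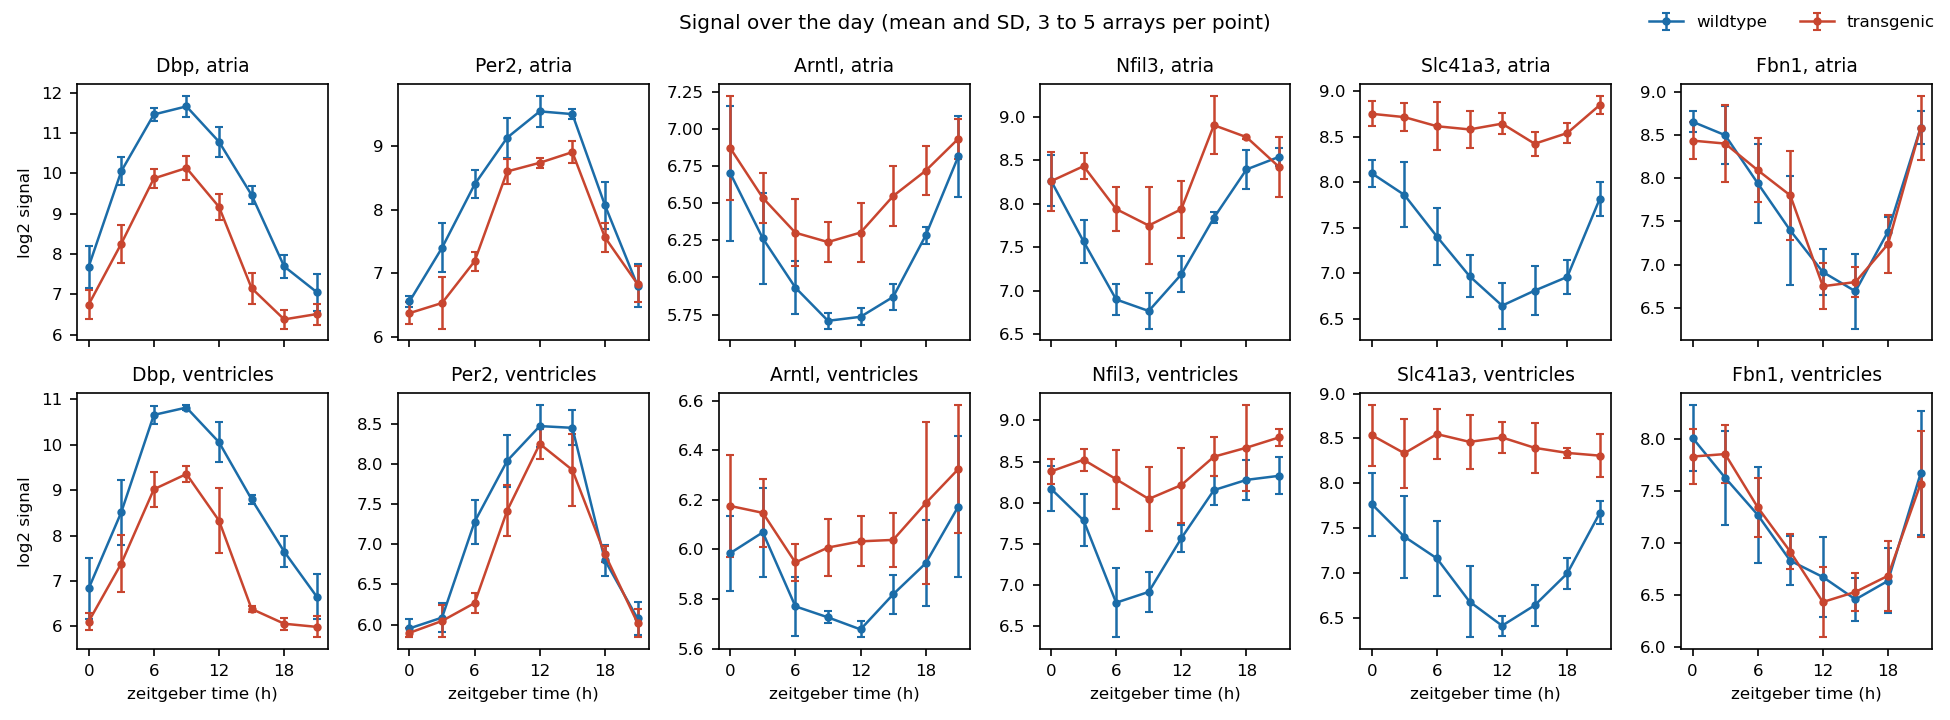
Mean log2 signal (y axis, a separate range in each panel) by zeitgeber time (x axis, h) of 6 genes in atria (top) and ventricles (bottom), wildtype in blue and transgenic in red, with bars of 1 SD over 3 to 5 arrays. The curves of Slc41a3 are nearly level in transgenic tissue (amplitude 0.13 in atria), while those of Fbn1 overlap in both genotypes (0.99 and 0.92 in atria).

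These 3 genes in atria and these 2 in ventricles were all that passed limma's test of the rhythm difference. An unadjusted p under 0.05 was found for 500 of 11275 genes in atria and 263 of 11604 in ventricles. Neither count is above the share of 0.05 that chance alone would give. Adjusted over the wildtype-rhythmic genes alone, the rhythm differed in 34 genes of the atria and 16 of the ventricles. Choosing genes for a wildtype rhythm favours a smaller transgenic one, and 9 and 7 of 100 splits by permuted genotype, the real one included, gave as many, so that chance cannot be excluded for these counts. Nfil3 was among them in both tissues (0.43 against 0.91 in atria, adjusted p = 0.00276, and 0.29 against 0.76 in ventricles, adjusted p = 0.00748). So were Per3 (0.61 against 0.96, adjusted p = 0.0150, and 0.33 against 0.57 with adjusted p = 0.0156, where transgenic Per3 was detected in 21 of 32 arrays and background limits its trough) and Rcan1, an inhibitor of calcineurin (0.08 against 0.40 and 0.01 against 0.51). The call of 4732462B05Rik was lost in the authors' table and without any 1 time point, and that of Cdkn1a in the authors' table and without ZT3, ZT6, ZT9 or ZT15. With time as a factor neither Slc41a3 nor Cdkn1a was called in ventricles, where the count was 0 (263 genes at an unadjusted p under 0.05 in the 24 h limma model). The count of 3 was 8 without transgenic animal 316 and 5 without transgenic animal 240. The count of 34 was 91 without ZT12, 15 without ZT21, 22 without transgenic animal 289, 21 without transgenic animal 233 and 19 without wildtype animal 279. It was also 21 in the authors' table and 22 with added 12 h terms. Array weights gave 13 in place of 3, 8 in place of 2 and 228 in place of 34. The count of 3 was 5 in the authors' table, without background correction or with 12 h terms, and the count of 2 was 1 without ZT3, ZT6, ZT9 or ZT15. The count of 16 was 6 without ZT0, 7 without ZT9, 9 without ZT21, 8 with time as a factor, 25 with array signal as a covariate and 44 with array weights.

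By their own test 168 genes were rhythmic in transgenic atria and 61 in transgenic ventricles, with 104 and 31 of them also rhythmic in the wildtype tissue. The count for atria was 61 without ZT15 and 529 with array weights, and that for ventricles 31 without ZT15, 40 without ZT12, 39 with transgenic arrays alone and 274 with array weights. Over the wildtype-rhythmic genes, the median share of the wildtype rhythm kept in transgenic tissue was 0.528 in atria (jackknife SE 0.210) and 0.641 in ventricles (SE 0.137). Genes chosen for a high wildtype rhythm give a share below 1 by selection. Without ZT12 the share was 0.311 in atria. In 1 random draw, genes were chosen in 16 of the wildtype animals and measured in the others. The median transgenic projection over that of the other wildtype animals was 0.807 in atria (309 genes) and 0.731 in ventricles (35 genes). This ratio of medians is not the same measure as the median share. The wildtype-rhythmic extracellular matrix genes kept a median share of 0.893 in atria (14 genes) and 0.980 in ventricles (4 genes). With 3 and 2 genes called over all genes, a test of lists against other genes could not decide. Adjusted over the list alone, the rhythm differed in 7 of 14 core clock and 6 of 10 clock output genes in atria, and in 3 of 14 and 4 of 10 in ventricles.

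**Figure D3:**
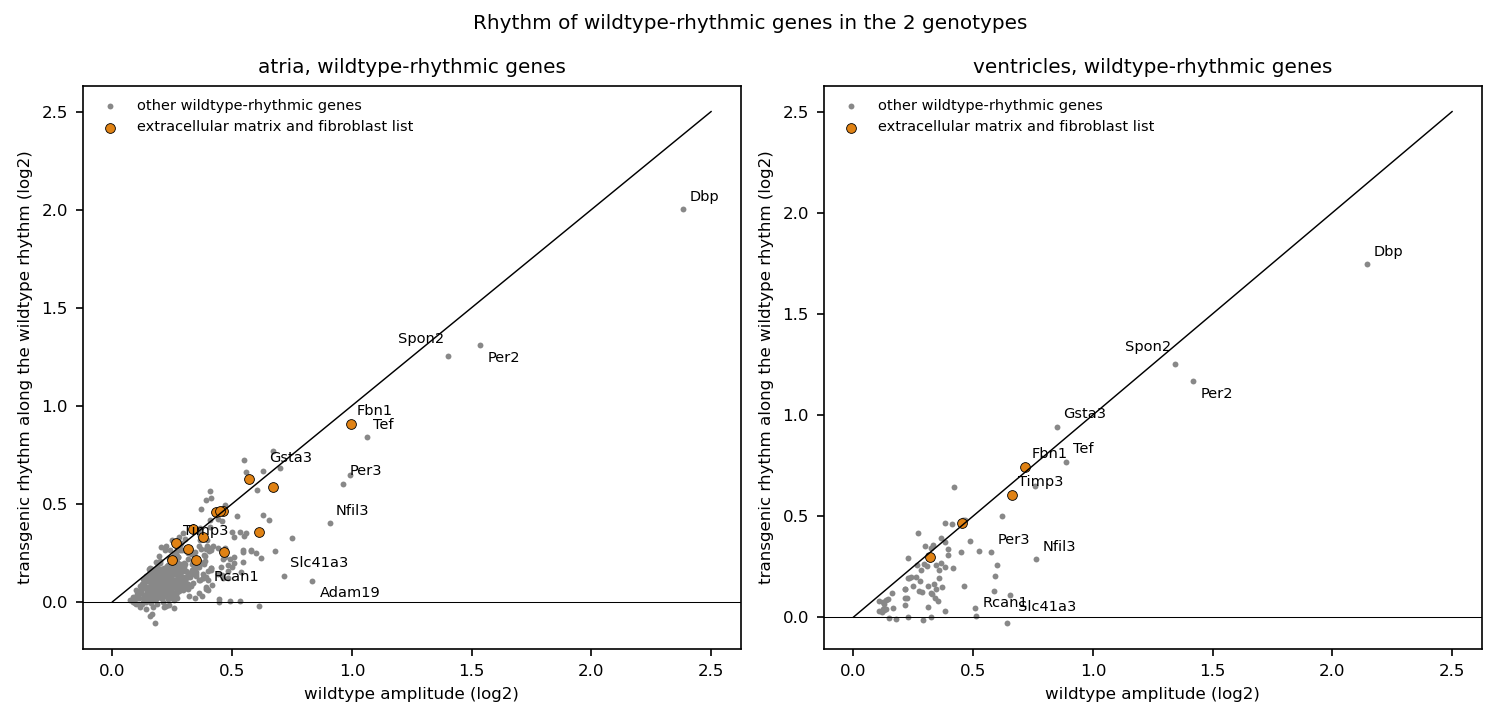
Transgenic rhythm along the direction of the wildtype rhythm (y axis, log2) against the wildtype amplitude (x axis, log2) of each wildtype-rhythmic gene in atria (left) and ventricles (right), with extracellular matrix and fibroblast genes in orange. Genes with an equal rhythm would lie on the diagonal line and genes without a transgenic rhythm at 0; Adam19 in atria (0.83 to 0.22 in amplitude) lies near 0.

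Levels averaged over the day were then compared between the genotypes, in atria first. Ces1d, a carboxylesterase that hydrolyses lipid esters, fell by 3.69 on the log2 scale (SE 0.124, 12.9-fold) in transgenic atria. Laptm4a, a lysosomal membrane protein, fell by 2.34 (SE 0.0609, 5.06-fold), and Ptgds, a prostaglandin D synthase, fell by 1.71 (SE 0.109, 3.28-fold). Dbp fell by 1.47 (SE 0.0972), Bdh1, an enzyme of ketone body oxidation, fell by 1.37 (SE 0.0643) to near background, and Prxl2a fell by 1.18 (SE 0.0708). Tef fell by 1.06 (SE 0.0563), and Opcml, an adhesion molecule, fell by 1.01 (SE 0.0719). Other Tef probes past the filter differed by only -0.02 and -0.07. Besides Clock, the largest rises were those of Myh7, the slow myosin heavy chain (1.80, SE 0.133, 3.48-fold), Slc41a3 (1.32, SE 0.0532, 2.49-fold), and Hcn2, a pacemaker channel (1.11, SE 0.0644, 2.16-fold). They were followed by Ankrd23, an ankyrin repeat protein of muscle (1.08, SE 0.0965), Prkg1, a kinase activated by cGMP (0.91, SE 0.0461), Pnpla3, a lipid droplet protein (0.89, SE 0.125), and Igsf1 (0.84, SE 0.0512). The adjusted p of these genes ranged up to 1.3e-07. Transgenic Bdh1 was detected in 2 of 32 atria arrays, so that background limits the size of its fall. The other Myh7 probe, detected in 24 of 64 atria arrays, differed by 0.04 (SE 0.0290).

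In atria 1523 genes differed in mean level by limma's moderated test, 838 higher and 685 lower in transgenic tissue, and 24 and 30 of them by at least 1.5-fold. The count was 982 without ZT9 and 1004 without ZT15. Among the 502 wildtype-rhythmic genes 188 differed in level. The clock output list shifted downward as a group. In it 6 of 10 genes fell (Dbp, Tef, Nampt, Usp2, Tspan4 and Klf9, 7 lower when adjusted over the list alone) and 2 rose (Nfil3 by 0.63 and Cdkn1a by 0.34, also 2 when adjusted over the list alone). The test of the list with camera gave an adjusted p = 4.5e-06, and adjusted p = 4.8e-05 with an estimated correlation. In the core clock list Clock and Arntl (0.40, SE 0.0522) rose. Per2 (-0.57, SE 0.0732), Per3 (-0.49, SE 0.0616), Bhlhe40 (-0.43, SE 0.0683), Rora (-0.37, SE 0.0601) and Nr1d2 (-0.29, SE 0.0606) were among those that fell. Transgenic Nr1d2 was detected in 7 of 32 arrays, so that background limits the size of its fall. The list had 2 higher and 6 lower of 14 genes, 2 and 7 when adjusted over the list alone (camera, adjusted p = 0.258).

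Genes of oxidative phosphorylation rose in transgenic atria, 16 of 38 (18 when adjusted over the list alone), by small steps: Cox7a1 by 0.36 (SE 0.0355), Ndufa2 by 0.27 (SE 0.0460), Cox5a by 0.21 (SE 0.0411) and Cox8b by 0.16 (SE 0.0309). The list median was 0.10 (camera, adjusted p = 2.2e-06, and adjusted p = 0.00589 with an estimated correlation). Heat shock and protein folding genes rose in 6 of 25, 7 when adjusted over the list alone (Hsp90ab1 by 0.31, SE 0.0441, and Dnaja4 by 0.35, SE 0.0669, adjusted p = 0.00946, but adjusted p = 0.220 with an estimated correlation). Muscle atrophy, ubiquitin and autophagy genes rose in 4 of 22, 5 when adjusted over the list alone (Becn1 0.24, Atg12 0.14, Psmb5 0.25 and Sqstm1 0.18, adjusted p = 0.0172, but adjusted p = 0.136 with an estimated correlation). Of 11 genes typical of the atrial chamber Dkk3 (-0.45), the connexin Gja5 (-0.65) and Nr2f1 (-0.23) fell, also 3 when adjusted over the list alone (adjusted p = 0.0135, but adjusted p = 0.220 with an estimated correlation). Markers of the epicardium and mesothelium, the cells that cover the heart, fell in 5 of 9, 7 when adjusted over the list alone (Tbx18 -0.28, Msln -0.30, Wt1 -0.28, C3 -0.22 and Lrrn4 -0.11, adjusted p = 2.3e-04, but adjusted p = 0.136 with an estimated correlation). With scores of ventricular, adipocyte and epicardial markers as covariates, chosen after the data were seen, 2 of these 6 lists still passed, clock outputs and oxidative phosphorylation (adjusted p = 5.5e-05 for each). The epicardium list is part of these scores, so that its loss follows from their construction.

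Other groups changed member by member in transgenic atria, and camera did not pass the threshold for the list. Fatty acid oxidation genes were higher in 7 of 24 and lower in 1, the same counts when adjusted over the list alone. Pdk4 (0.83), Acadm (0.53) and Cpt1b (0.23) rose, and the coactivator Ppargc1a fell by 0.49. Camera gave adjusted p = 0.0591, and adjusted p = 0.0348 in the authors' table. It gave adjusted p = 0.454 with an estimated correlation and adjusted p = 0.653 with marker scores as covariates. Triglyceride genes were higher in 4 and lower in 2 of 16, the same when adjusted over the list alone (Pnpla3 0.89 and Agpat3 0.42 rose, Dgat2 fell by 0.88 and Plin4 fell by 0.22; adjusted p = 0.240). Ketone and amino acid catabolism had 4 higher and 5 lower of 15, the same when adjusted over the list alone (Bdh1 -1.37, Glul -0.56, Dbt -0.39 and Bckdhb -0.32; adjusted p = 0.382). Ion channel and junction genes had 7 higher and 3 lower of 30, 8 and 3 when adjusted over the list alone (Hcn2 1.11, Kcnd2 0.59, Cacna1g 0.33 and Gja5 -0.65, adjusted p = 0.119). Another Kcnd2 probe differed by only 0.08. Genes of adrenergic and insulin signalling had 5 higher and 3 lower of 28, 6 and 5 when adjusted over the list alone (the insulin receptor substrate Irs1 0.52 and Pik3r1 -0.34; adjusted p = 0.664). In the fetal and hypertrophy list Myh7 and Rcan1 (0.61) rose and Mef2c (-0.29) fell among 21 genes, the same when adjusted over the list alone (adjusted p = 0.348). Another Rcan1 probe differed by only 0.07. Of 6 ventricular chamber genes only Myh7 passed, with or without adjustment over the list alone. Myl2 had a difference of 0.57 (SE 0.750) and Myl3 of 0.76 (SE 0.352). Camera gave adjusted p = 0.0560 for this list, and adjusted p = 0.0377 in the authors' table. It gave adjusted p = 0.454 with an estimated correlation.

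In ventricles the largest fall was again that of Ces1d. It fell by 4.09 (SE 0.0664, 17.1-fold). Bdh1 fell by 3.67 (SE 0.0876, 12.7-fold, to a signal detected in 20 of 32 transgenic arrays), Laptm4a fell by 2.47 (SE 0.0861, 5.53-fold) and Ptgds fell by 2.07 (SE 0.106, 4.19-fold). Dbp fell by 1.44 (SE 0.120), Prxl2a fell by 1.42 (SE 0.0783), Tef fell by 1.24 (SE 0.0833), and Rhobtb1 fell by 1.22 (SE 0.0818). Other Tef probes past the filter differed by only -0.05 and -0.05. Besides Clock, Slc41a3 (1.34, SE 0.0693, 2.54-fold), Hcn2 (1.15, SE 0.0886, 2.22-fold), the histone H4 genes H4c8 (2.01-fold) and H4c11 (1.77-fold), Slc17a7, a transporter of glutamate (0.98, SE 0.0727), Metrn (0.97, SE 0.0808) and the RNA-binding protein Igf2bp2 (0.80, SE 0.0621) rose most. Wildtype Slc17a7 was detected in 17 of 34 arrays, so that background limits its rise. The adjusted p of these genes ranged up to 5.9e-09.

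In ventricles 628 genes differed in mean level by limma's moderated test, 324 higher and 304 lower, of which 21 and 30 by at least 1.5-fold. Of the 90 wildtype-rhythmic genes 37 differed. The clock output list again shifted downward, with 5 of 10 lower (Dbp, Tef, Nampt at -0.97, Usp2 at -0.85 and Tspan4 at -0.15) and Nfil3 (0.67) and Cdkn1a (0.59) higher, or 6 lower and 2 higher when adjusted over the list alone (camera, adjusted p = 1.1e-04, and adjusted p = 3.0e-04 with an estimated correlation). Core clock genes had 2 higher (Clock and Arntl at 0.21, both near background in wildtype tissue, where Arntl was detected in 11 of 34 arrays) and 4 lower (among them Bhlhe40 -0.53, Per2 -0.31 and Per3 -0.28) of 14, 2 and 5 when adjusted over the list alone (adjusted p = 0.676). Of 16 macrophage markers Laptm5 (-0.32) and Adgre1 (-0.18) fell, also 2 when adjusted over the list alone (adjusted p = 0.0318, but adjusted p = 0.421 with an estimated correlation and not past the threshold in the authors' table). Oxidative phosphorylation had 2 of 38 higher, Cox7a1 by 0.40 and Cox8b by 0.12, also 2 when adjusted over the list alone (adjusted p = 0.0572). Fatty acid oxidation had 3 of 29 lower, also 3 when adjusted over the list alone (Ech1 -0.27, Hadhb -0.18 and Acaa2 -0.12, adjusted p = 0.186). Heat shock genes had 4 of 24 higher, also 4 when adjusted over the list alone (Hsph1 0.44, Stip1 0.34, Hsp90ab1 0.22 and Chordc1 0.16, adjusted p = 0.0722). Triglyceride genes had 2 higher and 2 lower of 18, 3 and 3 when adjusted over the list alone (Pnpla3 0.61, Cidea 0.30, Dgat2 -0.83 and Plin4 -0.36, adjusted p = 0.845). Without the 6 ventricle arrays of low signal 607 genes differed in level.

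The tissues were compared directly with both tables normalized together. Bdh1 had a difference of -3.78 (SE 0.0890) in ventricles and of -1.20 (SE 0.0903) in atria (ventricles minus atria -2.57, SE 0.127, adjusted p = 1.1e-36). Its transgenic signal lay near background in both tissues (log2 levels of 6.26 in ventricles and 5.75 in atria), while its wildtype level was higher in ventricles (10.04) than in atria (6.95), so that this difference depends on the wildtype levels. Myh7 was higher in transgenic atria (1.87, SE 0.124) and had a difference of -0.30 (SE 0.122) in ventricles (-2.17, SE 0.174, adjusted p = 5.4e-20). Prune2 had 0.71 (SE 0.0942) in atria and -0.35 (SE 0.0928) in ventricles (-1.06, SE 0.132, adjusted p = 9.2e-10). Opcml had -0.91 (SE 0.0478) in atria and 0.02 (SE 0.0471) in ventricles (0.93, SE 0.0671, adjusted p = 3.6e-23). Cilp2, a matrix protein, had 0.82 (SE 0.0734) and -0.01 (SE 0.0723) (-0.83, SE 0.103, adjusted p = 9.2e-10). The ventricle signals of Opcml (detected in 1 of 34 wildtype and 0 of 32 transgenic arrays) and Cilp2 (1 of 34 and 1 of 32) were background, so that a genotype difference there could not be measured. Amy2, an amylase, had -0.16 (SE 0.0771) and -0.97 (SE 0.0759) (-0.80, SE 0.108, adjusted p = 1.3e-08). In wildtype tissue the rhythm of Gja5, a connexin of the atria, had an amplitude of 0.55 in atria, with a peak at ZT 5.85, and of 0.10 in ventricles (adjusted p = 0.00618). Its wildtype level was low in ventricles (6.27 against 10.12 in atria), so that background limits its amplitude there.

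By limma's moderated tests 120 of 12201 genes differed between tissues in their genotype difference, 52 more positive in ventricles and 68 in atria, and 110 of them also with the animal as a block, where the count was 132. The wildtype rhythm differed in 3 genes, Gja5, Stx11 and the interleukin receptor Il18r1 (673 at an unadjusted p under 0.05), in 9 with the animal as a fixed block, in 5 with it as a random block, in 6 with array weights, in 1 without the filter on dim probes and in 13 with each tissue normalized on its own. It was 5 without each of animals 218, 294, 351, 231, 307, 285, 219, 317 and 321. The call of Stx11 was lost without background correction, and those of Stx11 and Il18r1 without the filter on dim probes. Of the 10678 genes tested in both tissues, 208 were higher and 157 lower in transgenic atria and ventricles alike. These were 365 in total where 41.3 would be expected by chance, while 5 went in opposite directions. The wildtype rhythm was called in both tissues for 67 genes where 4.03 would be expected, and 61 of these peaked within 2 h of each other.

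**Figure D4:**
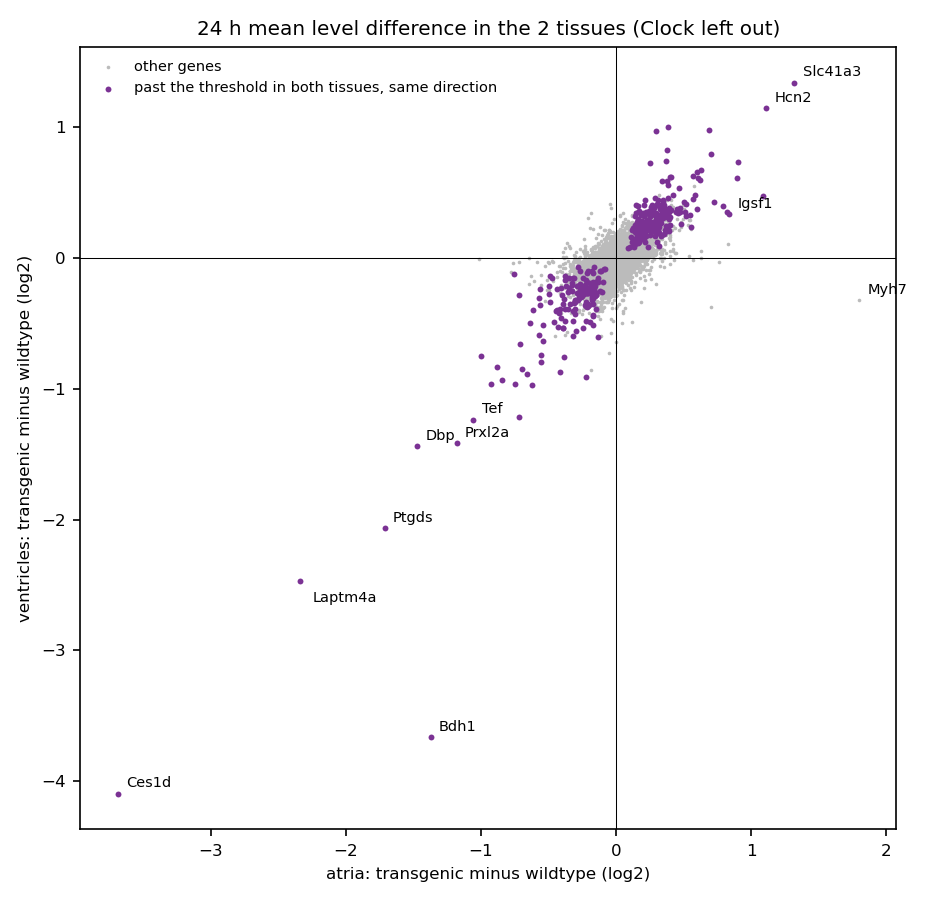
Transgenic minus wildtype mean level (log2) in ventricles (y axis) against atria (x axis), 1 point per gene tested in both tissues, by its brightest probe in each tissue, with Clock left out; purple points passed the threshold in both tissues with the same direction. Most named genes lie near the diagonal from Ces1d (-3.69 and -4.09) to Slc41a3 (1.32 and 1.34), while Myh7 (1.80 and -0.32) lies apart.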

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

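The tests of 1 segment as the source of all shared differences, of rhythms in cells without the transgene and both tests of Myh7 were chosen only after the result was seen. Differences between the tissues were singled out by limma's test of the difference itself. The genotype difference in level differed between tissues in 120 genes (highest of the other splits 1, so that chance can be excluded). The largest, as ventricles minus atria on the log2 scale, were Bdh1 (-2.57), Myh7 (-2.17), Prune2 (-1.06), Opcml (0.93), Cilp2 (-0.83) and Amy2 (-0.80), and Clock differed by -0.58. The wildtype rhythm differed in 3 genes, Gja5 by a length of 0.64, Stx11 by 0.30 and Il18r1 by 0.20. Of the 100 splits 2, the real one included, gave 3 genes or more, a share under 0.05 but not adjusted for the number of comparisons. The highest other split gave 35 genes, several times the real count, so that chance was not firmly excluded. This points to a possible structure of the samples that was not tested. Stx11 and Il18r1 lay near background in ventricles (log2 levels of 6.01 and 5.72), as did Gja5 (6.27) in wildtype ventricles, Opcml and Cilp2 in ventricles of both genotypes, Bdh1 in transgenic tissue and Clock in wildtype tissue, so that the sizes for these genes depend on background.

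The first pattern weighed is the set of 365 genes with a level difference of the same direction in both tissues. A sequence variant under a single probe is argued against as the source of the whole set. Of 91 other probes of these genes 71, or 78.0% (95% interval 68.1 to 86.0), had a difference of the same sign in both tissues. The count takes the sign alone, whatever its size, and probes of 1 gene are not independent. Among those counted, that of Igfbp5 had -0.62 in atria and -0.57 in ventricles, and that of Bdh1 only -0.03 and -0.01. A variant therefore stays open for single genes. A single chromosome segment from another strain is argued against as the source of all of them, since 91.3% of the 344 genes with a known place lay off the chromosome that held most. Such segments stay open for part of the set: 24 neighbouring pairs were found where random sets had a median of 13 (permutation p = 0.0036), and neighbouring genes may also share regulation. The pairs were spread over 13 chromosomes, and only 1 pair was among the 55 genes over 1.5-fold. The genotype itself stays open as an untested biological explanation.

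The second pattern is the median share of 0.528 of the wildtype rhythm kept in transgenic atria. Selection of genes with a high wildtype amplitude could account for it, since 25 of the 100 splits by permuted genotype, the real one included, gave a share as low. Genes chosen in a part of the wildtype animals gave 0.807, a ratio of medians from 1 random draw and not the same measure. Rhythms that persist in cells without the transgene may hold the share up for some genes, but this was not decided. The 14 rhythmic matrix genes kept 0.893 where the others kept 0.515 (one-sided permutation p = 2e-04). The permutation treated genes as independent, while the matrix list had an estimated correlation of 0.208. It did not match genes for wildtype amplitude, and which cells express them was not measured. A loss of rhythm in heart muscle cells by genotype stays open for the other genes.

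The third pattern is Myh7, higher by 1.80 (SE 0.133) in transgenic atria. Ventricular tissue in the atrial samples is argued against as the whole cause, since the difference was 1.47 (SE 0.0991, 95% interval 1.27 to 1.67) with Myl2 and Myl3 as covariates, although it could account for the part between these values. A probe that reads another transcript stays open: the other Myh7 probe differed by 0.0443 (SE 0.0290), but it was detected in 24 of 64 atria arrays and lay too near background to decide. A difference of the atria by genotype stays open as an untested biological explanation.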

How the results depend on the processing

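The alternatives on array signal, low-signal arrays, low-weight arrays and marker scores were chosen after seeing the data. Of 61449 values of single genes under an alternative, 60087 kept direction and side of the threshold, 896 lost and 465 gained a call, and 1 turned: Myl2 in atria became -1.01 with marker scores, which hold Myl2 itself. The causes of the changes below were not tested, and remarks in brackets such as fewer arrays only describe the setting. Array weights gave 1449 rhythmic genes in wildtype atria, 529 in transgenic atria, 186 and 274 in wildtype and transgenic ventricles, 13 and 8 rhythm differences in atria and ventricles, 228 and 44 adjusted over wildtype-rhythmic genes, a kept share of 0.474 in ventricles and 6 wildtype rhythm differences between tissues. Time as a factor gave 264 rhythmic genes in wildtype atria and 0 and 8 rhythm differences in ventricles over all and over wildtype-rhythmic genes. The 24 h limma model had 263 of 11604 genes at an unadjusted p under 0.05 there, no more than chance alone would give. The authors' table gave 5 and 21 rhythm differences in atria and 1 list in ventricles, no background correction 5, and 12 h terms 5 and 22. No filter gave 334 rhythmic genes in wildtype atria and 1 wildtype rhythm difference between tissues (more genes tested), and separate normalization gave 13. Transgenic arrays alone gave 39 rhythmic genes in ventricles (fewer arrays). Without ZT6, ZT9, ZT12, ZT15 and ZT21 wildtype atria had 324, 225, 765, 307 and 300 rhythmic genes. Without ZT15 transgenic atria had 61 and transgenic ventricles 31, and without ZT12 the latter had 40. The 34 rhythm differences of the atria became 91 without ZT12 and 15 without ZT21. Level differences in atria became 982 without ZT9 and 1004 without ZT15. The 2 rhythm differences in ventricles became 1 without ZT3, ZT6, ZT9 or ZT15, and the 16 became 6, 7 and 9 without ZT0, ZT9 and ZT21 and 25 with array signal as a covariate. The kept share in atria was 0.311 without ZT12, and in ventricles 0.491 for genes rhythmic in atria. For genes chosen in some animals the ratio of medians was 0.807 in atria. Lists past the threshold in atria rose from 6 to 9 in the authors' table and fell to 2 with marker scores (which hold the epicardium list itself) and to 2 with an estimated correlation, and in ventricles from 2 to 1 with an estimated correlation. Leaving out 1 animal at a time gave 366 to 764 rhythmic genes in wildtype atria (764 without wildtype 205), 138 to 206 in transgenic atria, 78 to 101 in wildtype and 46 to 70 in transgenic ventricles. It gave 2 to 8 rhythm differences in atria (8 without transgenic 316, 5 without transgenic 240), 19 to 39 over wildtype-rhythmic genes (22 and 21 without transgenic 289 and 233, 19 without wildtype 279), and 2 to 3 and 13 to 21 in ventricles. Level differences ranged from 1362 to 1681 in atria and 558 to 713 in ventricles, the kept share from 0.424 to 0.560 and 0.611 to 0.694. Between tissues the ranges, with the animal as a block among them, were 107 to 132 and 2 to 9, the latter 5 with a random block and 5 without each of animals 218, 294, 351, 231, 307, 285, 219, 317 and 321. Without the 6 low-signal arrays ventricles had 82 wildtype and 53 transgenic rhythmic genes and 607 level differences. Without the arrays of low weight, wildtype atria had 542 rhythmic genes and ventricles 534 level differences. Signal near background limits dim genes such as Clock in wildtype tissue.

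Of the 100 splits, the real one included, 1 gave as many rhythmic genes as wildtype atria (502, highest other 9) and 1 as transgenic atria (168 and 1), 2 as wildtype ventricles (90 and 331) and 3 as transgenic ventricles (61 and 155). Chance can be excluded for atria but not firmly for ventricles. There, high counts in other splits point to a possible untested structure of the samples. For the rhythm differences 2 splits in atria (3 and 632) and 4 in ventricles (2 and 998) gave as many. These shares lie under 0.05 but were not adjusted for the number of comparisons. With so many calls in other splits, chance was not firmly excluded for these small counts. Adjusted over wildtype-rhythmic genes, 9 splits in atria (34 and 454) and 7 in ventricles (16 and 55) gave as many, and chance cannot be excluded. For level differences it can, with 1 split in atria (1523 and 2), 1 in ventricles (628 and 3), 1 for the difference between tissues (120 and 1) and 1 for the overlap (365 and 0). A kept share as low came in 25 splits in atria (0.528, lowest other 0.139) and 9 in ventricles (0.641, lowest other 0.411), and as many lists passed in 8 splits in atria (6, highest other 8) and 23 in ventricles (2 and 4), so that chance cannot be excluded for these shares and counts. List by list, a camera p as small came in 1 split for clock outputs in each tissue and for oxidative phosphorylation in atria. In atria it came in 2 for epicardium, 3 for heat shock, 4 for muscle atrophy and 6 for atrial chamber genes. For macrophage markers in ventricles it came in 13.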

Other observations

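The alternative with marker scores as covariates was chosen after the data were seen. No other test in this part was chosen after the result was seen. In transgenic atria glucose and glycogen genes were higher in 5 and lower in 4 of 31, 7 and 5 when adjusted over the list alone (the hexokinase Hk1 0.35, SE 0.0541, and the glycogen phosphorylase Pygb 0.26, SE 0.0543; camera, adjusted p = 0.338). Cardiomyocyte genes were higher in 5 and lower in 1 of 21, 7 and 1 when adjusted over the list alone (the sarcomere genes Mybpc3 0.52, SE 0.0578, and Tcap -0.41, SE 0.0597). Camera gave adjusted p = 0.123, and adjusted p = 0.0377 in the authors' table. It gave adjusted p = 0.454 with an estimated correlation and adjusted p = 0.776 with marker scores as covariates. Endothelial markers were higher in 1 and lower in 4 of 18, the same when adjusted over the list alone (Emcn -0.25, SE 0.0501, Vwf -0.21, SE 0.0553, and Ly6c1 0.26, SE 0.0764; adjusted p = 0.844). Immediate early genes were lower in 3 of 16, with 1 higher and 3 lower when adjusted over the list alone (Ier3 -0.66, SE 0.0777, Klf6 -0.25, and Junb -0.20; adjusted p = 0.0956). The endoplasmic reticulum list had Dnajb11 (0.29) higher and the transcription factor Xbp1 (-0.19) lower of 18, 2 and 2 when adjusted over the list alone (adjusted p = 0.844). Glucocorticoid-responsive genes had Pdk4 (0.83) higher and Mt1 (-0.44) and Klf9 (-0.23) lower of 16, 1 and 3 when adjusted over the list alone (adjusted p = 0.376). The cholesterol and fatty acid synthesis list had Insig2 (0.13) higher and Scd2 (-0.27) and Fads1 (-0.17) lower of 17, 2 and 2 when adjusted over the list alone (adjusted p = 0.611). In the extracellular matrix list Col4a2 (0.25) rose and Tgfb3 (-0.19) fell of 33, 1 and 0 when adjusted over the list alone (adjusted p = 0.914).

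Smaller lists in atria had few calls, which were the same when adjusted over the list alone: Acta2 (-0.63) and Rgs5 (0.21) of 11 smooth muscle genes, Tnni2 (-0.76) and Eno3 (0.20) of 6 skeletal muscle genes, Ccnd2 (-0.23) of 12 cell cycle genes, Cd8b1 (0.25) of 5 lymphocyte genes, Cox8b (0.16) of 10 adipocyte genes and Dbh (0.23), an enzyme of noradrenaline synthesis, of 6 nerve genes. In transgenic ventricles ketone and amino acid genes had Bdh1 (-3.67), Glul (-0.80) and Bckdhb (-0.59) lower of 15, with 2 higher and 5 lower when adjusted over the list alone (adjusted p = 0.0580). Adrenergic and insulin genes had Irs1 (0.41), Adcy5 (0.34) and Prkar1a (0.24) higher and the adrenergic receptor Adrb1 (-0.29) and Pik3r1 (-0.35) lower of 27, the same when adjusted over the list alone (adjusted p = 0.487). Muscle atrophy genes had Gabarapl1 (0.33), Sqstm1 (0.28) and Map1lc3a (0.26) higher of 22, with 3 higher and 1 lower when adjusted over the list alone (adjusted p = 0.106). The fat synthesis enzymes Fasn (-0.40) and Acaca (-0.18) fell of 17 cholesterol and fatty acid synthesis genes, also 2 when adjusted over the list alone (adjusted p = 0.186). Of 18 endoplasmic reticulum genes Xbp1 (-0.22) and P4hb (-0.17) fell, 3 when adjusted over the list alone (adjusted p = 0.0820). Of 15 immediate early genes Ier3 fell by 0.89, also 1 when adjusted over the list alone (adjusted p = 0.676).

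Arrays of the same animal were weakly alike after tissue, genotype and time were taken out. Over 1000 genes the median correlation across genes between the atria and ventricle arrays of 1 animal was 0.0629, where it was -0.00064 between different animals, and genes are not independent replicates. The correlation was over 0.1 in 27 of 64 pairs of the same animal (42.2%) and in 36.0% of the pairs of different animals. For 6 of the 64 atria arrays the closest ventricle array was that of the same animal, where 0.97 would be expected by chance, and the consensus correlation of arrays of 1 animal was 0.0146.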
